A study of Trametes versicolor and Gelatoporia subvermispora with 30 samples.

How the data were processed

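RNA sequencing was carried out on 30 libraries from the white-rot fungi Trametes versicolor and Gelatoporia subvermispora, which were grown in a defined minimal medium of the Czapek-Dox type. Each species had 5 culture conditions with 3 libraries each: cellobiose alone (5 g per litre), cellobiose with 2 mM 4-hydroxybenzoic acid (4HBA), cellobiose with 2 mM syringic acid, cellobiose with lignin isolated from poplar (25 mg in 25 mL), and 2 g of milled poplar in 25 mL without cellobiose. Per the labels, total RNA was depleted of ribosomal RNA with a kit made for yeast and turned into stranded libraries. The labels do not say whether the 3 replicates of a group were separate cultures, so every p-value measures only the spread between these libraries. The numbers in the sample labels follow a low line for lignin and syringic acid and no such mark for cellobiose, 4HBA and poplar. The labels do not say whether these series were cultured or sequenced apart.

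The deposited values are unnormalized counts of reads per gene, and they were read as such after whole numbers and differing library totals were found in every file. The submitters' processing notes name FastQC, Bowtie2, Bowtie and HTSeq. Their versions, settings and genome builds are not given in the sources used here. The files pair gene numbers with locus tags or symbols and hold no product names. Of the 14570 T. versicolor genes, 14560 were found in the reference table for that species. No reference table was at hand for the 12313 G. subvermispora genes, so no coordinates are given for them. Reads that the authors' counting could not place in a gene made up 45.8% to 48.7% of all counts in 6 of the T. versicolor libraries and 9.60% to 14.2% in the other 9. The same share was 24.2% to 27.9% in 4 of the G. subvermispora libraries and 7.84% to 9.89% in the other 11. These entries were left out of every test.

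Gene counts summed to 16.7 to 50.4 mega-counts (M) per T. versicolor library and to 24.7 to 50.3 M per G. subvermispora library. The limit that a count of 0 allows, set at 3 counts, came to between 0.0613 and 0.205 normalised CPM (counts scaled to a common library size) in T. versicolor and to between 0.0431 and 0.225 CPM in G. subvermispora. Intervals and limits of this kind cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate libraries of a group differed by more than counting error: chi-square per gene, over genes with at least 20 counts in a pair, was 7.24 to 61.5 in T. versicolor and 11.1 to 4255 in G. subvermispora. Both pairs with 4HBA replicate 1 of G. subvermispora, a library unlike the others of its group, were at 3820 and 4255, and the highest of the other pairs was at 304. No pair was a copy of another.

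Counts were normalized with the TMM method and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, all tests being two-sided. The 15 libraries of a species were fitted together with 1 mean per group. Genes passed edgeR's default expression filter, which left 12295 genes in T. versicolor and 10860 in G. subvermispora. The biological coefficient of variation was 0.110 and 0.150. A gene was said to rise or fall when its Benjamini-Hochberg adjusted p over all tested genes was below 0.05. Levels are TMM-normalized CPM with the standard deviation over 3 libraries. Log2 changes of genes come from the edgeR fit with its default prior count, and log2 CPM values used a prior count of 2. Each species had 6 comparisons: the 4 additions or substrates against cellobiose, syringic acid against 4HBA, and lignin against syringic acid. These choices, the alternatives tried and the rule for naming genes were fixed before the data were examined, except where stated.

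The 43 gene lists planned at that stage relied on product names, which the files lack. Of those lists, 1 matched any name, the T. versicolor symbols DyP1 and DyP2. Lists were therefore built from the symbols in the files, 11 for T. versicolor and 17 for G. subvermispora, after the symbols had been seen. A symbol stands for the enzyme class its name abbreviates, and the counts alone cannot check that. Lists of at least 3 tested genes were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, and again with the correlation estimated. Among the members of gene families with closely similar sequences, such as the peroxidases, the authors' counting could split or drop shared reads, so single members are less certain than families. The responses of 7 lists present in both species were compared with a species-by-condition interaction in limma on the mean log2 CPM of each list, 28 tests in all.

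The naming rule took, against cellobiose, up to 8 genes with the largest rise and 8 with the largest fall among symbols that passed the test, reached a mean of 10 CPM in the higher group and had no overlap between both sets of 3 libraries. Chance gives such a separation to 10% of genes for 3 libraries against 3. It added up to 2 members of each list in either direction, and up to 4 symbols in either direction for comparisons between additions. Because few genes have symbols, locus tags that met the same thresholds and had the largest changes were added after the values were seen. They are given for 4HBA only. Members named outside this rule are said to have been chosen after their values were seen.

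Libraries were also sorted by the share of gene counts in their 10 most abundant genes, above or below 20%, a division made after the data were seen and called library type here. Within-type comparisons and fits with library type as a second term use the same edgeR test. The other alternatives were RLE and upper-quartile normalization, no expression filter, DESeq2 1.42.0, fits of the compared groups alone, a 2-fold minimum, and leaving out each library in turn. Fits without genes above 1% of counts and with a gene-length offset for T. versicolor were added after the data were seen. The pipeline was tested on simulated data with added changes of 1.5-, 2-, 4- and 8-fold between 4HBA and cellobiose. It recovered 56%, 82%, 94% and 98% of them in T. versicolor and 58%, 88%, 100% and 100% in G. subvermispora, and unchanged genes made up 7.82% and 5.46% of its calls. Apart from these changes the simulated libraries of a species shared 1 mean profile. The rates therefore do not cover library type or other differences between groups. Figures were drawn with matplotlib 3.10.9.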

Results

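Transcript levels were measured by RNA sequencing in Trametes versicolor and Gelatoporia subvermispora, white-rot basidiomycetes that degrade the lignin of wood. The title of the study asks about lignin catabolism inside the cell. Mycelium of each species was grown on cellobiose, on cellobiose with 4-hydroxybenzoic acid (4HBA), syringic acid or poplar lignin, or on milled poplar wood. 4HBA and syringic acid are aromatic acids related to units of lignin. There were 3 libraries in each of the 5 groups per species. Gene counts per library, in mega-counts (M), were 23.8, 23.8 and 24.4 M for T. versicolor on cellobiose and 23.3, 22.3 and 23.5 M with 4HBA. They were 26.8, 16.7 and 22.8 M with syringic acid, 24.5, 24.5 and 27.3 M with lignin, and 42.2, 50.4 and 44.0 M on milled poplar. For G. subvermispora they were 31.1, 34.7 and 34.2 M on cellobiose and 31.3, 42.5 and 48.6 M with 4HBA. They were 28.5, 25.6 and 38.4 M with syringic acid, 24.7, 25.4 and 33.3 M with lignin, and 50.3, 42.8 and 46.9 M on milled poplar.

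The libraries fell into 2 types by the share of gene counts taken by their 10 most abundant genes. In T. versicolor that share was 41.9% to 48.4% in the 6 cellobiose and 4HBA libraries and 3.84% to 7.45% in the 9 others. In G. subvermispora it was 32.7% to 43.5% in the 3 cellobiose libraries and 4HBA replicate 1, and 4.07% to 7.95% in the remaining 11. Reads outside annotated genes moved with it, at 21.1% to 22.1% against 6.25% to 9.52% of counts in T. versicolor and 21.5% to 23.6% against 6.86% to 8.56% in G. subvermispora. Library type therefore coincides with the addition of syringic acid, lignin or poplar in T. versicolor, where no fit can separate them in a comparison against cellobiose. Comparisons of 4HBA with cellobiose, of lignin with syringic acid, and of poplar with lignin or syringic acid stay within 1 type in that species. In both species poplar against lignin or syringic acid crosses the label series, with and without a low line. Poplar against cellobiose stays within 1 label series but crosses library type. In G. subvermispora the mixed 4HBA group allows library type to be fitted as a term. With that term 85 of 142 values for named genes kept direction and call, 53 lost the call and 4 reversed. The 142 include syringic acid against 4HBA and lignin against syringic acid, where no call was lost. Few losses were on poplar. For 4HBA, syringic acid and lignin against cellobiose, most named values lost the call or reversed. The term rests on 4HBA replicate 1, and the standard error grew in 53 of these 57 values, by a median factor of 1.68, while the change itself shrank to a median of 0.702 of its first size. The first change lay outside the 95% interval of the fit with the term in 7 of the 57, all of them TOR1 or TOR2. The other values had on the whole smaller changes with wider spreads, and do not tell library type from the addition. In each of the 12 comparisons the majority direction among called genes turned under at least 1 other scaling or fit, so the counts of rises and falls below give no overall direction.

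**Figure D1:**
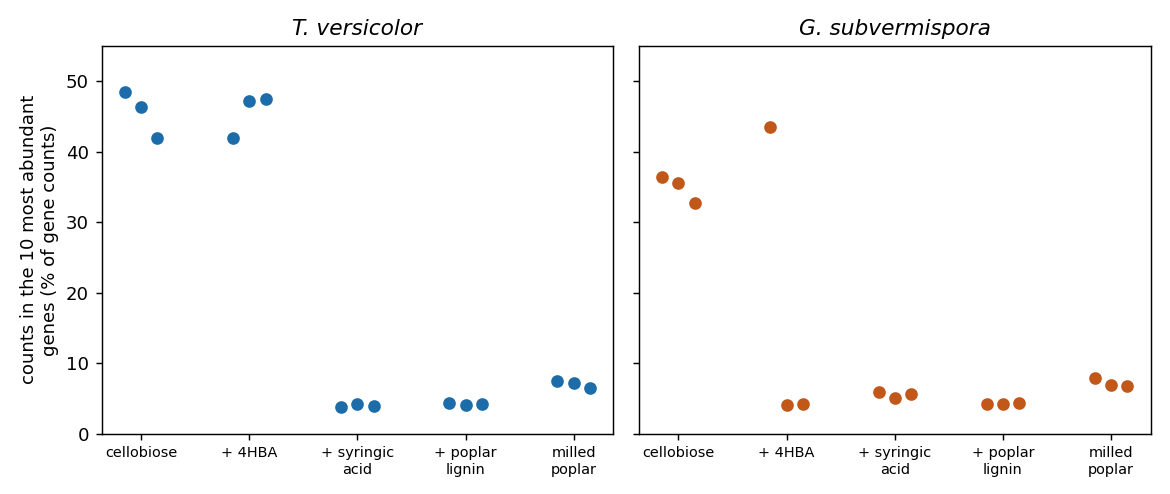
Share of each library's gene counts taken by its 10 most abundant genes, in percent, for the 5 culture conditions of each species; each point is a library. The T. versicolor cellobiose and 4HBA libraries lie between 41.9% and 48.4%, and 4HBA replicate 1 of G. subvermispora, at 43.5%, lies apart from the other 4HBA libraries.

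With 4HBA, T. versicolor raised a laccase, a secreted copper enzyme that oxidises phenols, and lowered several secreted peroxidases. Levels are given as normalised CPM, read counts scaled to a common library size. TvLac3 rose from 50.4 ± 9.0 to 216 ± 55.7 CPM (SD, n = 3; log2 change 2.10, adjusted p = 0.000178). The manganese peroxidase MnP5s, of a class that oxidises manganese(II) to an attacker of phenolic lignin, fell from 100.0 ± 19.2 to 34.1 ± 10.8 CPM (log2 change -1.55, adjusted p = 0.00183). MnP3s fell by 1.37 on the log2 scale, the dye-decolorizing peroxidase DyP1 by 1.65, the heme-thiolate peroxidase HTP1 by 0.79 and LDO1 by 0.72. Of the 13 manganese peroxidases 0 rose, 4 fell and 9 did not pass the test, and adjusted over the list alone 1 rose and 5 fell. Among 10 lignin peroxidases, secreted heme enzymes of high redox potential, 1 rose and 1 fell, with a median of 0.10, a mean of 0.02 and camera direction down. The 26 class II peroxidases together, a family of secreted fungal heme peroxidases, had 1 rise and 5 falls, or 2 and 6 adjusted over the list alone. Of the 7 laccases 1 rose and 0 fell, and the list-alone counts of laccases and lignin peroxidases were the same. VP2, a versatile peroxidase of the same family chosen after its values were seen, was at 546 ± 75.5 CPM against 409 ± 61.6 CPM and was not called.

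Many genes with the largest changes had no symbol, so a few locus tags with the largest rises and falls are given by number. They were added after the values were seen, under the same thresholds as the symbols. TRAVEDRAFT_45010 rose from 2.32 ± 0.451 to 146 ± 76.8 CPM (n = 3 each; log2 change 5.98) and TRAVEDRAFT_170215 from 40.5 ± 6.04 to 1219 ± 408 CPM (log2 change 4.91). TRAVEDRAFT_24504 fell from 10.6 ± 5.03 to 0.441 ± 0.278 CPM (log2 change -4.60) and TRAVEDRAFT_21780 from 23.9 ± 5.77 to 1.90 ± 0.543 CPM (log2 change -3.65). In total 2011 of 12295 genes were called by edgeR, 1107 up and 904 down, and 181 of the rises and 209 of the falls were at least 2-fold. The count was 1265 without 4HBA replicate 1.

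Syringic acid was accompanied in T. versicolor by lower levels of a further laccase and of a versatile peroxidase. TvLac1 fell from 324 ± 62.5 to 77.7 ± 28.3 CPM (SD, n = 3; log2 change -2.06) and VP2 from 409 ± 61.6 to 108 ± 28.5 CPM (log2 change -1.92). MnP5s fell by 2.76 on the log2 scale, LDO1 by 1.37, HTP1 by 1.25, TvLac2 by 0.92 and TvFet3A, a ferroxidase of high-affinity iron uptake, by 0.83. TvLac3 rose by 1.26 to 121 ± 33.2 CPM and TvLac4 by 0.45. Of the 7 laccases 4 rose and 2 fell, of the 10 lignin peroxidases 5 rose and 1 fell, and of the 13 manganese peroxidases 2 rose and 4 fell. The same counts held when adjusted over the list alone. The 15 tested of 268 transfer RNA genes, a class that total-RNA libraries capture unevenly, had 6 rises and 0 falls, beside the change of library type in this comparison. In all 6090 genes were called, 3330 up and 2760 down. Under upper-quartile scaling, which moved the median of all genes by 0.13 on the log2 scale, the split was 4597 up and 1952 down, and with RLE normalization it was 2959 up and 3059 down.

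Lignin was accompanied by the highest TvLac3 level of the 5 groups. TvLac3 stood at 392 ± 116 CPM against 50.4 ± 9.0 CPM on cellobiose (SD, n = 3; log2 change 2.96, adjusted p = 2.31e-06). HTP3 rose by 2.24 on the log2 scale, the lignin peroxidase LiP1 by 0.95 and TvLac4 by 0.69. VP2 fell from 409 ± 61.6 to 96.9 ± 21.5 CPM (log2 change -2.08), and MnP5s fell by 2.25, HTP1 by 1.97, MnP3s by 1.79, LDO1 by 1.76, TvLac1 by 1.23 and TvFet3A by 0.94. The manganese peroxidases had 1 rise and 6 falls among 13, the lignin peroxidases 4 rises and 1 fall among 10, and the laccases 3 rises and 1 fall among 7. Adjusted over the list alone the counts were 1 and 6, 4 and 2, and 3 and 1. The class II peroxidases had 5 rises and 8 falls among 26, with 8 of each under upper-quartile scaling. Of the 15 transfer RNA genes 4 rose, or 3 adjusted over the list alone. The comparison called 6138 genes, 3313 up and 2825 down, and 4541 up and 2021 down under upper-quartile scaling, which moved the median by 0.13. With RLE normalization the split was 2918 up and 3120 down.

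On milled poplar 1 manganese peroxidase of T. versicolor rose from a low level while most of the others fell. MnP7s rose from 0.497 ± 0.270 to 75.4 ± 3.73 CPM (SD, n = 3; log2 change 7.20, adjusted p = 6.15e-14), while MnP5s fell from 100.0 ± 19.2 to 1.01 ± 0.126 CPM (log2 change -6.62). VP2 fell from 409 ± 61.6 to 11 ± 0.382 CPM (log2 change -5.21) and TvLac1 from 324 ± 62.5 to 24.5 ± 2.64 CPM (log2 change -3.73). MnP1s fell by 4.35 on the log2 scale, MnP3s by 4.31, HTP1 by 3.07, TvFet3A by 2.21, MnP10s by 2.08, TvLac2 by 1.85 and DyP1 by 1.41. Of the 13 manganese peroxidases 2 rose, 7 fell and 4 were not called, and the 7 laccases had 0 rises and 4 falls. These counts did not change when adjusted over the list alone. Of the 3 versatile peroxidases 2 fell, and of the 10 lignin peroxidases 4 rose, or 3 adjusted over the list alone.

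Within library type, poplar against lignin gave a log2 change of 6.16 for MnP7s, -4.37 for MnP5s, -3.14 for VP2 and -2.49 for TvLac1. Against syringic acid the changes were 6.22 for MnP7s, -3.86 for MnP5s, -3.30 for VP2 and -1.67 for TvLac1. LDO1 fell by 1.39 on the log2 scale against cellobiose, differed from syringic acid by -0.02 and rose by 0.36 against lignin. The lignin peroxidases, with 4 rises and 0 falls against cellobiose, had 4 rises and 3 falls against lignin (median -0.07) and 4 of each against syringic acid (median -0.14). The comparison with cellobiose called 8752 genes, 4394 up and 4358 down, of which 1774 rises and 1965 falls were at least 2-fold. Poplar against lignin called 9438 genes and poplar against syringic acid 8910.

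**Figure D2:**
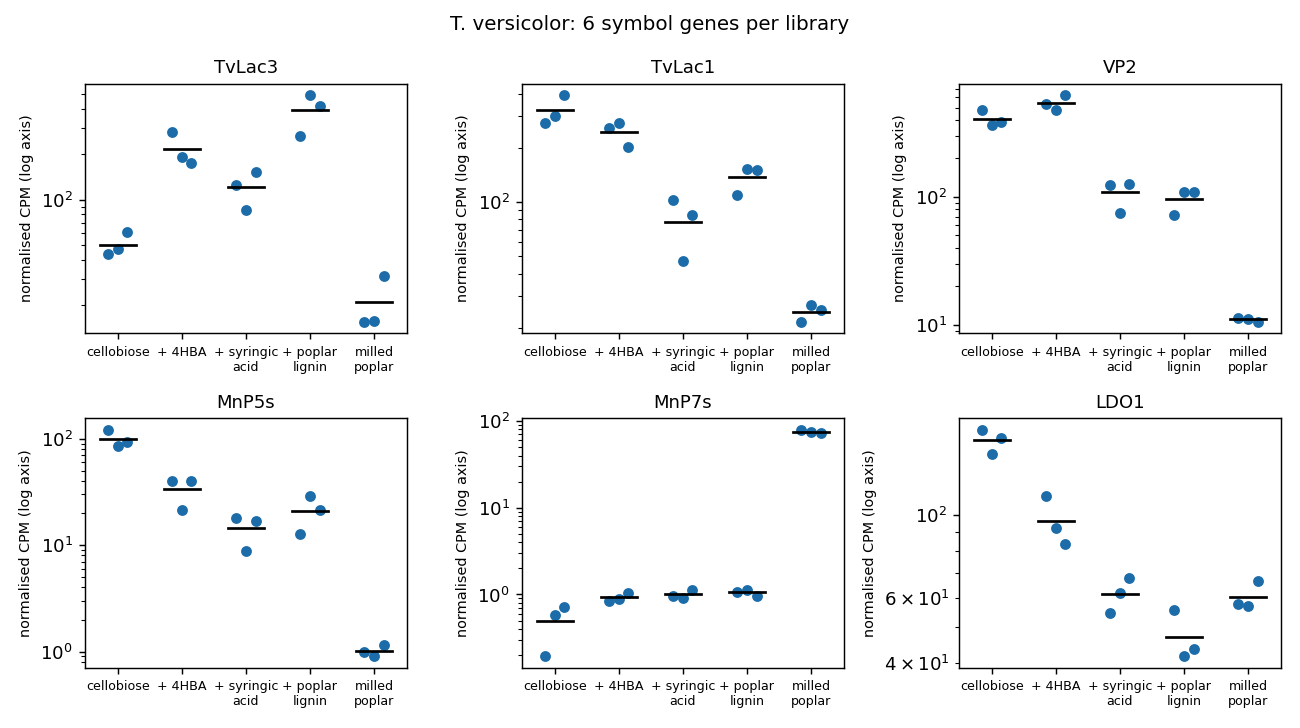
Normalised CPM, on log axes, of 6 T. versicolor genes in the 5 culture conditions; points are libraries and bars are means of 3. MnP7s lies at 75.4 CPM on milled poplar and below 2 CPM in every other library, and TvLac3 is highest with lignin, at a mean of 392 CPM.

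4HBA, a para-hydroxybenzoic acid, and syringic acid, which also carries a methoxy group on either side of the hydroxyl, were compared at the same 2 mM in T. versicolor. VP2 was lower with syringic acid than with 4HBA, at 108 ± 28.5 against 546 ± 75.5 CPM (SD, n = 3; log2 difference -2.33, adjusted p = 3.20e-07). TvLac1 was lower by a log2 difference of -1.65 and MnP5s by -1.21. DyP1 was higher with syringic acid by 1.21, MnP3s by 0.76 and the cytochrome c peroxidase CCP1, a mitochondrial enzyme, by 0.42. MnP8s differed by -0.02 (95% interval -0.40 to 0.37), was not called, and was chosen after its values were seen. Manganese peroxidases had 3 higher and 1 lower among 13, or 2 and 1 adjusted over the list alone. Laccases had 1 higher and 3 lower among 7, which became 4 higher and 3 lower under upper-quartile scaling. The median laccase difference was 0.30, the mean -0.19 and the camera direction down. Of 15 transfer RNA genes 9 were higher and 0 lower.

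TvLac3, at 121 ± 33.2 CPM with syringic acid and 216 ± 55.7 CPM with 4HBA, differed by -0.84 on the log2 scale (adjusted p = 0.0241), a call lost without 4HBA replicate 1, syringic replicate 1 or syringic replicate 2. Both acids differed in 5929 genes, 3227 higher and 2702 lower with syringic acid. The split was 4915 and 1868 under upper-quartile scaling, which moved the median by 0.16, and 2754 and 3029 with RLE normalization, and library type differs between these groups.

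Lignin and syringic acid, which share a library type in T. versicolor, differed in fewer genes. TvLac3 was at 392 ± 116 CPM with lignin and 121 ± 33.2 CPM with syringic acid (SD, n = 3; log2 difference 1.70, adjusted p = 0.00176). MnP3s was lower with lignin by a log2 difference of -1.17 and HTP1 by -0.72. The laccases had 3 higher and 1 lower among 7, or 4 and 1 adjusted over the list alone. Manganese peroxidases had 0 higher and 2 lower among 13, or 0 and 3 adjusted over the list alone. TvLac1 was called higher with lignin by 0.82, but not without lignin replicate 2, lignin replicate 3 or syringic replicate 3. The count of 1075 genes, 486 higher and 589 lower, was 344 when both groups were fitted alone. It was 525, 696, 646, 547 and 2258 without lignin replicate 1, lignin replicate 2, syringic replicate 1, syringic replicate 3 and syringic replicate 2.

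Over the 6 T. versicolor comparisons camera called 0 lists after adjustment and 5 at an unadjusted p below 0.05. With an estimated correlation it again called 0, and no other set test was run. The smallest adjusted p belonged to the manganese peroxidases with 4HBA (0.0798, direction down).

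In G. subvermispora, 4HBA lowered a lignin peroxidase, raised a heme-thiolate peroxidase and moved manganese peroxidases in both directions. LiP2 fell from 1134 ± 129 to 439 ± 28.0 CPM (SD, n = 3; log2 change -1.37, adjusted p = 9.56e-06) and MnP1 from 196 ± 40.6 to 69.0 ± 12.1 CPM (log2 change -1.51). MnP10 rose from 8.66 ± 2.68 to 30.7 ± 9.71 CPM (log2 change 1.81) and HTP7 from 348 ± 24.2 to 679 ± 101 CPM (log2 change 0.97). CsMn25 fell by 1.42, ter14 by 1.19, acl4 by 1.11 and CsMn38 by 0.97 on the log2 scale, while CsPh10, a mating pheromone by its symbol, rose by 0.78 and the transporter mfs1 by 0.61. The 13 manganese peroxidases had 2 rises and 3 falls, the 9 heme-thiolate peroxidases 1 rise and 1 fall, and the 7 laccases 0 rises and 1 fall. These counts were the same adjusted over the list alone. The median was 0.04 and the mean -0.15 for the manganese peroxidases, and 0.15 and -0.05 for the laccases, with camera direction down for each. Locus tags were again added after the values were seen. Among them, CERSUDRAFT_140923 rose from 7.59 ± 0.895 to 228 ± 22.0 CPM and CERSUDRAFT_98642 by 4.01 on the log2 scale. CERSUDRAFT_90765 fell by 3.93 and CERSUDRAFT_136772 by 3.18.

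Against cellobiose, 4HBA replicate 1, the 4HBA library of the same type, gave a log2 change of -1.27 for LiP2, -1.26 for MnP1, 1.12 for HTP7 and 4.80 for CERSUDRAFT_140923. A single library has no spread of its own, so the standard errors here rest on the spread of other groups. Over the whole 4HBA group the laccase Cslcs2, the ferroxidase Csfet3 and the nutrient-sensing kinases TOR1 and TOR2 fell by 1.25, 1.19, 0.35 and 0.68. In replicate 1 the changes were -1.14 (SE 0.46) for Cslcs2 and -1.12 (SE 0.37) for Csfet3, close to the whole group with a wider spread. They were -0.11 (SE 0.11) for TOR1 and -0.17 (SE 0.12) for TOR2, which shrank. The whole group gave 3417 called genes, 1901 up and 1516 down, or 1675 up and 1712 down with RLE normalization. The fit with library type as a term gave 844, and 2216 were called without 4HBA replicate 2.

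With syringic acid the laccase Cslcs7 and PRX5 rose in G. subvermispora. Cslcs7 went from 6.16 ± 0.240 to 206 ± 164 CPM (SD, n = 3; log2 change 5.06) and PRX5 from 154 ± 9.47 to 1132 ± 363 CPM (log2 change 2.87). CsMn06 rose by 2.20 on the log2 scale, the laccase Cslcs1 by 1.44 and the cytochrome c peroxidase CCP by 1.07. The pheromone symbol CsPh12 fell from 250.1 ± 28.7 to 45.6 ± 23.4 CPM (log2 change -2.45), acl4 fell by 2.43, ter14 by 2.28, HTP7 by 2.07 and CsPh5 by 1.65. Of the 22 genes in the mating-type list, which holds pheromone and pheromone receptor symbols and others such as mip, 4 rose and 10 fell. The manganese peroxidases had 1 rise and 3 falls among 13, the heme-thiolate peroxidases 2 rises and 3 falls among 9, and the laccases 2 rises and 1 fall among 7. Adjusted over the list alone the laccases had 2 rises and 0 falls, and the counts of the other lists named here were the same. The heme-thiolate peroxidases had a median of 0.14, a mean of -0.31 and camera direction down. Cellobiose and syringic libraries differ in type: 6137 genes were called, 2912 up and 3225 down, or 3173 up and 2934 down without genes above 1% of counts, and 2705 with library type as a term. HTP4 and LiP2 were no longer called with it: HTP4 went from -1.52 (SE 0.26) to -1.46 (SE 0.52), a wider spread at a like fold, and LiP2 from -0.38 (SE 0.12) to -0.23 (SE 0.20), a smaller fold as well.

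Lignin was accompanied in G. subvermispora by rises of Cslcs1 from 403 ± 61.7 to 1083 ± 57.0 CPM (SD, n = 3; log2 change 1.43) and of CsMn06 and CsMn33 by 1.42 and 1.15 on the log2 scale. CsPh12 fell from 250.1 ± 28.7 to 59.3 ± 8.12 CPM (log2 change -2.08), CsPh5 by 1.35, acl4 by 1.11, CsMn38 by 0.99 and ter14 by 0.91. The manganese peroxidases had 1 rise and 4 falls among 13, the heme-thiolate peroxidases 0 rises and 3 falls among 9, the laccases 2 rises and 1 fall among 7, and the mating-type list 5 rises and 7 falls among 22. Adjusted over the list alone the mating-type list had 6 rises and 7 falls, and the other counts were the same. Its median was 0.03, its mean -0.08 and its camera direction down. MnP2, which fell from 802 ± 151 to 158 ± 27.8 CPM, and HTP7, which fell by 1.30, were not called once library type was a term. MnP2 went from -2.35 (SE 0.53) to -2.0 (SE 1.00) and HTP7 from -1.30 (SE 0.21) to -1.07 (SE 0.33), with smaller folds and wider spreads. The counts were 5138 genes, 2659 up and 2479 down, or 2497 up and 2661 down with RLE normalization, and 1232 with library type as a term.

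On milled poplar G. subvermispora raised most of its manganese peroxidases and heme-thiolate peroxidases. MnP6 rose from 20.5 ± 0.608 to 897 ± 236 CPM (SD, n = 3; log2 change 5.45, adjusted p = 1.31e-11) and HTP7 from 348 ± 24.2 to 6298 ± 1235 CPM (log2 change 4.18). MnP3 rose by 4.60, HTP5 by 4.50, MnP8 by 4.14 and HTP8 by 4.00 on the log2 scale. CsMn01 rose by 5.04, the transporter msf2 by 4.83, the laccases Cslcs1 and Cslcs2 by 2.66 and 2.16, and the multicopper oxidase Csmco1 by 1.96. Csfet3 fell from 429 ± 113 to 36.6 ± 8.07 CPM (log2 change -3.55), LiP2 from 1134 ± 129 to 314 ± 23.1 CPM (log2 change -1.85), ter14 by 3.60, CsMn38 by 2.10 and CCP by 1.89.

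Of the 13 manganese peroxidases 9 rose and 4 fell on poplar, and of the 9 heme-thiolate peroxidases 7 rose and 2 fell. Of the 16 class II peroxidases 10 rose and 5 fell, or 11 and 5 adjusted over the list alone, of the 7 laccases 4 rose and 2 fell, and all 6 ter genes fell. Other list-alone counts were the same. Camera gave adjusted p = 0.0216 for the manganese peroxidases (up; adjusted p = 0.128 with an estimated correlation, 0.00211 to 0.128 over the alternatives). For the heme-thiolate peroxidases it gave 0.00321 (up; adjusted p = 0.128 with an estimated correlation, 0.000485 to 0.128 over the alternatives). The class II list had 0.0487 (up; adjusted p = 0.212 with an estimated correlation, range 0.0107 to 0.212), and was called in 6 of 9 alternatives, where each of the other 3 lists was called in 8. The ter genes had 0.0222 (down; adjusted p = 0.128 with an estimated correlation, range 0.0166 to 0.128).

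Within library type, poplar against lignin gave log2 changes of 5.50 for MnP6, 5.48 for HTP7, -4.22 for Csfet3 and -1.20 for LiP2, and 9 of 13 manganese peroxidases rose. Against syringic acid the changes were 5.71 for MnP6, 6.25 for HTP7, -3.46 for Csfet3 and -1.47 for LiP2, and again 9 rose. The laccases, with a median of 0.37 against cellobiose, had 3 rises and 2 falls against lignin (median 0.50) and 3 of each against syringic acid (median -0.50), which itself raised Cslcs7 and Cslcs1. MnP2 and HTP4, called lower against cellobiose by 2.06 (SE 0.53) and 0.59 (SE 0.24), were not called lower against lignin, and HTP4 rose by 0.93 against syringic acid. With library type as a term they were at -1.71 (SE 0.99) and -0.52 (SE 0.52), smaller changes with wider spreads that were not called. The HTP4 call was also lost without poplar replicate 1 or cellobiose replicate 1 or 2. The comparison with cellobiose called 8264 genes, 4090 up and 4174 down. Under upper-quartile scaling, which moved the median by -0.28, the split was 3012 up and 5408 down, and with RLE normalization 4232 up and 4048 down.

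**Figure D3:**
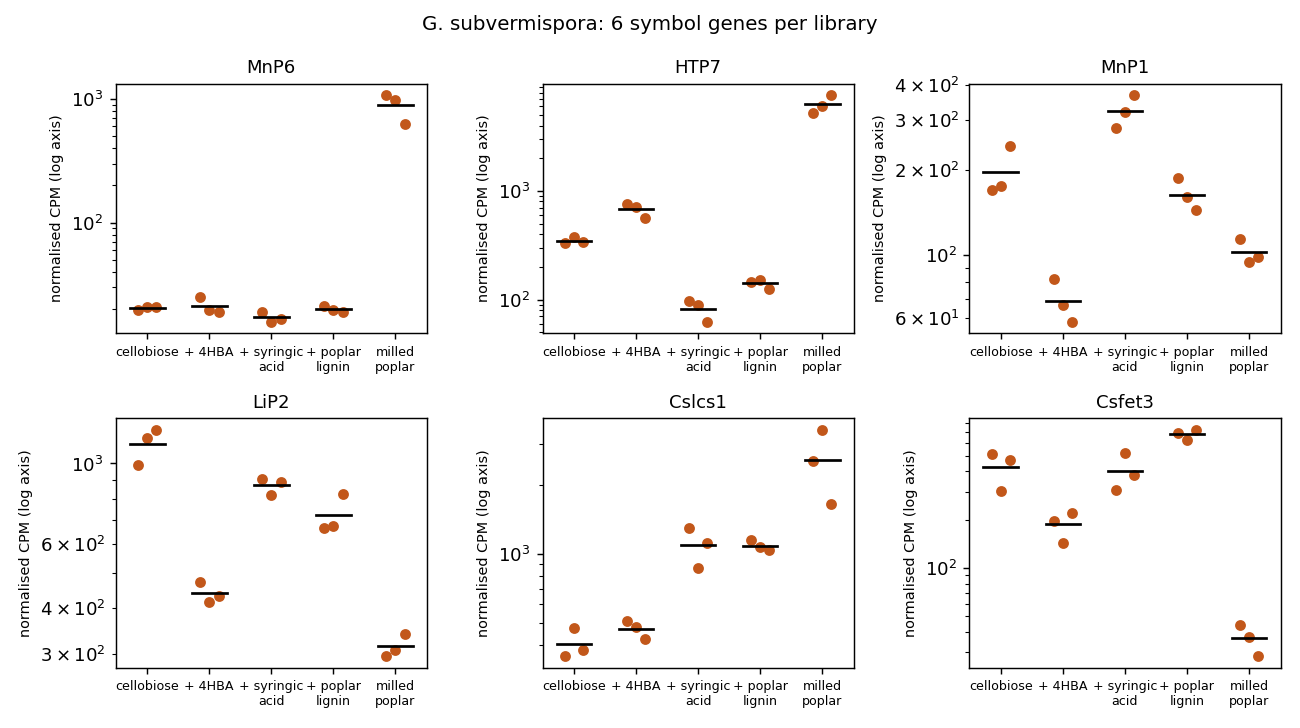
Normalised CPM, on log axes, of 6 G. subvermispora genes in the 5 culture conditions; points are libraries and bars are means of 3. On milled poplar MnP6 averages 897 CPM and HTP7 6298 CPM, while Csfet3 averages 36.6 CPM; HTP7 is lowest with syringic acid, at a mean of 82.6 CPM.

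The same pair of acids at 2 mM differed in G. subvermispora in HTP7, Cslcs7 and MnP1. HTP7 was at 82.6 ± 17.7 CPM with syringic acid and 679 ± 101 CPM with 4HBA (SD, n = 3; log2 difference -3.04, adjusted p = 2.82e-07). MnP1 was at 323 ± 43 against 69.0 ± 12.1 CPM (log2 difference 2.23), Cslcs7 differed by 4.78, PRX5 by 2.05 and CsMn06 by 1.84. CsPh12 was lower with syringic acid by -1.66, nps1 by -1.45 and CsPh5 by -1.41. Of the 22 mating-type genes 2 were higher and 15 lower, or 2 and 16 adjusted over the list alone (camera down, adjusted p = 0.0235; adjusted p = 0.639 with an estimated correlation, 0.00600 to 0.639 over the alternatives). Of the 19 CsMn genes 8 were higher and 0 lower, or 6 and 0 adjusted over the list alone (camera up, adjusted p = 0.0308; adjusted p = 0.156 with an estimated correlation, 0.0159 to 0.156 over the alternatives). Manganese peroxidases had 3 higher and 5 lower among 13, with a median of -0.29, a mean of -0.02 and camera direction up. TOR1 differed by -0.02 between both acids (95% interval -0.24 to 0.20) and the laccase Cslcs6 by -0.13 (95% interval -0.36 to 0.11), and neither was called. These genes were chosen after their values were seen.

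Against 4HBA replicates 2 and 3 alone, which have the library type of the syringic libraries, HTP7 differed by -2.96, MnP1 by 2.37, Cslcs7 by 4.76 and PRX5 by 1.97. There 2 mating-type genes were higher and 16 lower. These groups still differ in label series, which is not separated from the acids. The counts were 5602 genes over the whole 4HBA group, 2415 higher and 3187 lower with syringic acid, and 5352 with library type as a term. The majority turned to 2836 higher and 2693 lower without genes above 1% of counts and also with both groups fitted alone (51.8% higher), so the balance of directions is not settled.

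Lignin against syringic acid, again within 1 library type, gave lower PRX5 and CCP with lignin in G. subvermispora. PRX5 was at 232 ± 18.5 CPM with lignin and 1132 ± 363 CPM with syringic acid (SD, n = 3; log2 difference -2.29, adjusted p = 4.82e-06), and CCP at 191 ± 21.0 against 502 ± 86.1 CPM (log2 difference -1.40). Cslcs7 was lower by -4.07, while acl4 was higher by 1.31 and Cslcs2 by 1.11. The CsMn genes had 0 higher and 5 lower among 19, the laccases 2 higher and 2 lower among 7 and the mating-type list 5 higher and 2 lower among 22. Adjusted over the list alone the laccases had 2 and 3, and the other counts were the same. Camera called 0 lists in this comparison, 1 at an unadjusted p below 0.05, the CsMn genes, and 0 with an estimated correlation. HTP7, higher with lignin by 0.77, was not called without lignin replicate 2 or syringic replicate 3. Called genes numbered 3653, 2029 higher and 1624 lower, or 1751 higher and 1825 lower with RLE normalization.

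Both species were then compared in how shared enzyme groups responded. On milled poplar the mean level of the manganese peroxidases moved by -1.28 on the log2 scale in T. versicolor and by 1.37 in G. subvermispora, a difference of 2.65 (limma interaction, adjusted p = 2.54e-10). The heme-thiolate peroxidases moved by -0.98 and 2.12, a difference of 3.10 (adjusted p = 6.31e-09). Laccases moved by -0.96 and 0.60 (difference 1.55, adjusted p = 1.13e-05), and cytochrome c peroxidase by 0.12 and -1.88 (difference -2.0, adjusted p = 1.96e-07). The ferroxidase group fell in both fungi, with changes of -2.19 and -3.53. That group and cytochrome c peroxidase hold 1 gene per species, so they are not family responses. Cellobiose and poplar libraries differ in library type in each species, but not to the same extent. Reads without an alignment made up 21.2% to 23.1% of all counts on cellobiose and 2.76% to 3.23% on poplar in T. versicolor. In G. subvermispora they made up 0.960% to 1.13% and 0.228% to 0.460%, so library type need not cancel in these differences. Of the 28 interactions 14 passed the test, single-gene contrasts among them. The lists were made from symbols, and the species contribute different numbers of genes to some of them.

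**Figure D4:**
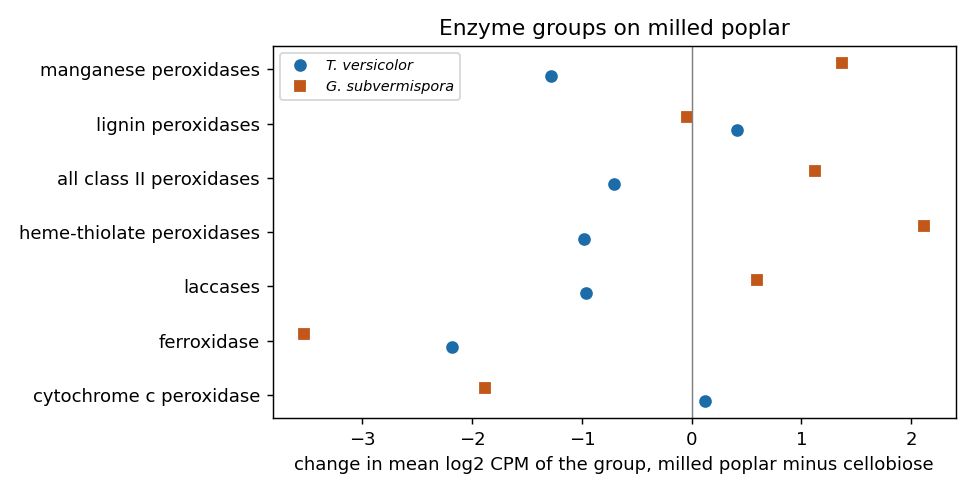
Change in the mean log2 CPM of 7 enzyme groups on milled poplar relative to cellobiose, for each species. Points are means over 3 libraries per condition. The ferroxidase and cytochrome c peroxidase groups hold 1 gene per species, and the class II group contains the manganese peroxidases. Manganese peroxidases lie at -1.28 in T. versicolor and 1.37 in G. subvermispora, and heme-thiolate peroxidases at -0.98 and 2.12.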

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

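The comparison of species within each enzyme group was planned before the results were seen, on lists made from the symbols in the files, while the test of poplar genes within library type was chosen after its result had been seen. These results are given because a group moved differently in each fungus under the same condition, by a test of the difference itself. Each value is the change in G. subvermispora minus that in T. versicolor in the mean log2 CPM of a group, from 3 libraries per condition and species. The ferroxidase and cytochrome c peroxidase groups hold 1 gene per species.

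On milled poplar the difference was 2.65 for manganese peroxidases, 1.83 for all class II peroxidases, a list that contains them, and 3.10 for heme-thiolate peroxidases. The adjusted p-values were 2.54e-10, 4.80e-09 and 6.31e-09 in limma. Laccases differed by 1.55 (adjusted p = 1.13e-05). In these 4 groups all 3 poplar libraries lay above all 3 cellobiose libraries in G. subvermispora and below them in T. versicolor. The ferroxidases differed by -1.35 (adjusted p = 0.00686) and cytochrome c peroxidase by -2.0 (adjusted p = 1.96e-07). Lignin peroxidases, also part of the class II list, differed by -0.45 and were not called (adjusted p = 0.106).

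With lignin the ferroxidases differed by 1.62 (adjusted p = 0.000999): Csfet3 was at 682 ± 51.8 CPM with lignin and 429 ± 113 CPM on cellobiose, TvFet3A at 108 ± 15 and 207 ± 48.3 CPM (SD, n = 3 each; limma). The rise of Csfet3 by itself (log2 change 0.67, SE 0.23) lost its call without cellobiose replicate 2 or 3 or lignin replicate 1 or 3. With library type as a term it was 0.78 (SE 0.43, adjusted p = 0.261), not called because of the wider spread. The heme-thiolate peroxidases differed by -0.63 with lignin (adjusted p = 0.0119) and cytochrome c peroxidase by -0.46 (adjusted p = 0.0257). The fit on list medians gave cytochrome c peroxidase an adjusted p of 0.0882 at the same difference. The median of 1 gene is its mean, so that fit does not check this value. With syringic acid cytochrome c peroxidase differed by 1.01 (adjusted p = 0.000999), laccases by 0.62 (adjusted p = 0.0176) and heme-thiolate peroxidases by -0.66 (adjusted p = 0.0203). Laccases and heme-thiolate peroxidases lost the call with list medians, at adjusted p-values of 0.0572 and 0.102. With 4HBA the heme-thiolate peroxidases differed by 0.32 and the ferroxidases by -1.06 (adjusted p = 0.0183 for each). With list medians the adjusted p was 0.111 for the heme-thiolate peroxidases, a lost call. For the ferroxidases it was 0.00558, which is no check either, since each list holds 1 gene. The 4HBA libraries of G. subvermispora are of both types and those of T. versicolor of 1 type, so library type enters the 4HBA differences of the species unequally. With lignin and syringic acid library type changes in both species. Reads without an alignment were 21.2% to 23.4% in 1 type and 2.76% to 4.25% in the other in T. versicolor. In G. subvermispora they were 0.960% to 1.88% and 0.207% to 1.02%. Library type therefore need not cancel in the lignin and syringic acid differences, and is not separated from the addition there.

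The poplar pattern was weighed against library type, which differs between cellobiose and poplar in both fungi. Of 67 symbol genes called at least 2-fold on poplar, 61 kept direction and call against both lignin and syringic acid, which have the library type of poplar. Lignin and syringic acid carry the other label series, so this check does not separate poplar from any difference between the series. This is 91.0% (exact 95% interval 81.5% to 96.6%), and it argues against library type as the whole cause for those genes. The interval treats genes as independent, which genes measured in the same libraries are not, so it is too narrow. The share was 90.8% of all 3739 such genes in T. versicolor and 90.3% of 3803 in G. subvermispora, so the symbol genes do not stand out, and the comparisons share the poplar libraries. The 6 others were LDO1 in T. versicolor and CsMn06, MnP2, Cslcs7, ter9 and acl4 in G. subvermispora, where syringic acid or lignin also moved several of them. The carbon source and the solid wood are both part of this contrast and are not separated by the design, so that a response to the substrate remains a hypothesis.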

How the results depend on the processing

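Fits with library type as a term, with the 4HBA library of the cellobiose type alone, without genes above 1% of counts and with a gene-length offset were chosen after the data were seen. Over all settings 2464 of 2653 values for named genes and species differences kept direction and call, 185 kept direction only and 4 reversed. These values were picked for passing the test in these data, and the settings refit the same values. A high share kept was therefore likely from the start and is no independent support. All 201 named values tried without an expression filter kept direction and call, as did 200 of 201 with DESeq2, 200 with upper-quartile scaling and 197 with RLE normalization. With library type as a term 85 of 142 did so, with 53 calls lost, and with the 4HBA library of the cellobiose type alone 10 of 26, with 16 lost. For 4HBA both of these settings compare replicate 1 with cellobiose, so the same contrast enters the total under each. Every call lost with the term was against cellobiose, and most were with 4HBA, syringic acid or lignin rather than on poplar. The species differences kept 10 of 14 calls with list medians, which is no check for lists of 1 gene per species. Of 1206 values with a library left out 1110 kept direction and call. The cause was not tested for any change below except where the setting itself gives it.

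A 2-fold minimum, which by construction calls fewer genes, left 390, 1040, 1068 and 3739 genes for 4HBA, syringic acid, lignin and poplar against cellobiose in T. versicolor, 907 for syringic acid against 4HBA and 181 for lignin against syringic acid. In G. subvermispora it left 380, 1269, 734 and 3803, with 1066 and 488. With library type as a term G. subvermispora gave 844 genes for 4HBA, 2705 for syringic acid and 1232 for lignin, and 4HBA replicate 1 alone against cellobiose gave 717, a fit in which that library is assumed to vary like the other groups. With that term 4 values reversed, none of them called: TOR2 with syringic acid (0.26), TOR1 with syringic acid (0.0047), TOR2 with lignin (0.14) and TOR2 on poplar (0.023). Lignin against syringic acid in T. versicolor gave 344 genes when both groups were fitted alone. Of the 6 lists called by camera 0 were called with an estimated correlation.

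Leaving out single libraries gave in T. versicolor 1265 to 1772 genes for 4HBA, 5121 to 6100 for syringic acid, 5084 to 5608 for lignin, 8237 to 8365 for poplar, 4839 to 6040 for syringic acid against 4HBA and 525 to 2258 for lignin against syringic acid. The G. subvermispora ranges were 2216 to 3728, 5276 to 5910, 4180 to 4644, 7838 to 8191, 4658 to 5357 and 2567 to 3363. Called lists ranged from 5 to 9 and called species differences from 13 to 19, against 14 with all libraries and 11 with list medians. Counts moved by more than 1.5 times without 4HBA replicate 1 of T. versicolor (1265), 4HBA replicate 2 of G. subvermispora (2216), and in lignin against syringic acid of T. versicolor without lignin replicates 1 (525) or 2 (696) or syringic replicates 1 (646), 2 (2258) or 3 (547). Sample numbers in the labels are shared only between cellobiose and syringic acid in G. subvermispora, after a low line in 1 of the groups, and nothing says that they mark a shared culture or day. With that number as a replicate block, chosen after the data were seen, both groups alone gave 6062 genes against 6420 without the block. Deviations from the group means correlated at -0.08, -0.07 and 0.10 for the shared numbers, and 1 of the 3 syringic libraries correlated best with its own number, so the numbers were not taken to pair the libraries. Depth was at least 16.7 mega-counts in every library, and genes near 0.2 CPM are at the counting limit.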

Other observations

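Tests of 4HBA replicate 1 with genes above 1% of counts left out were chosen after the result was seen. Expectations for the first slope, gene length, raised 4HBA neighbours and splits of libraries were written down before their results. Neighbour counts for lowered genes and other additions, and gene values by library type, had no such expectation. Symbols not described so far in G. subvermispora include genes of autophagy, the bulk recycling of cell contents. On milled poplar ATG27 rose from 47.0 ± 2.15 to 93.5 ± 19.9 CPM (SD, n = 3; edgeR) and ATG15B from 65.3 ± 1.01 to 115 ± 9.28 CPM, while the lipid kinase Vps34 fell from 31.6 ± 0.249 to 18.3 ± 1.88 CPM and ATG1 from 31.0 ± 1.00 to 20.7 ± 2.19 CPM. Of 11 autophagy genes 5 rose and 3 fell, both over all genes and adjusted over the list alone, and 3 rose and 4 fell under upper-quartile scaling. The pheromone symbol CsPh3 rose on poplar from 325 ± 39.2 to 1087 ± 341 CPM and the receptor symbol CsSTE3.5 by 1.31 on the log2 scale, and 13 of 22 mating-type genes rose and 5 fell. Of 19 CsMn genes 9 rose and 7 fell, and 9 rose and 10 fell under upper-quartile scaling. Within library type 8 rose and 7 fell against lignin (median -0.08) and 7 rose and 11 fell against syringic acid (median -0.28), and 9 rose and 5 fell against cellobiose with library type as a term. The mfs transporters had 3 rises and 1 fall among 5.

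The other lists gave these counts. On poplar both acl genes fell in G. subvermispora, acl3 by 0.68 and acl4 by 1.58 on the log2 scale, nps1 fell by 1.61, and the lignin peroxidases had 1 rise and 1 fall. Against syringic acid, which itself lowered acl4, acl3 fell by 0.47 and acl4 rose by 0.85, while both still fell with library type as a term. TOR2 fell by 0.82 (SE 0.18) on poplar, but with library type as a term its change was 0.023 (SE 0.15) and not called, so that fall is not separated from library type. In T. versicolor LDO2 fell by 0.79 on poplar, from 32.9 ± 0.194 to 19.1 ± 0.881 CPM. The 11 tested of 191 locus tags of G. subvermispora numbered with a t had 4 rises and 5 falls on poplar. CCP1 of T. versicolor fell by 0.37 with 4HBA, a call lost without cellobiose replicates 1 or 2 or any of the 4HBA replicates.

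Library type was set against 4HBA as an explanation for the 3781 genes called in G. subvermispora between 4HBA replicates 2 and 3 and cellobiose. Replicate 1, which has the library type of cellobiose, showed the same genes with a slope of 0.287 (95% interval 0.228 to 0.365) on replicates 2 and 3, where a slope near 0 would fit library type alone and a slope above 0.5 would speak against it. Without genes above 1% of counts, and with cellobiose libraries not shared between the axes, the slope was 0.428 (0.340 to 0.529) and 91.2% of genes had the same sign. Both slopes lie between these bounds, so the shares of 4HBA and library type in these genes cannot be told apart. In T. versicolor library type and addition coincide. Library type would move the same genes alike with lignin, and 75.6% of the genes called with syringic acid were also called with lignin in the same direction. Both comparisons use the same cellobiose libraries, so this overlap does not separate library type from the addition. Of the genes called with syringic acid 11.5% were also called between lignin and syringic acid, which does not separate them either.

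Gene length was set beside library type for the T. versicolor genes called with syringic acid. Across genes, which are not independent replicates, Spearman's rho between length and log2 change was -0.282 (95% interval -0.298 to -0.264) with syringic acid, -0.288 with lignin and -0.09 on poplar, and 0.07 with 4HBA, where library type does not change. A size of 0.3 had been set as the mark of a length effect and 0.1 as its absence, so gene length cannot be told apart from the addition as a contributor. With a gene-length offset 77.5% of the calls kept their direction and call, which argues against a length trend as the whole cause. A change in library preparation between the groups may contribute, and no biological explanation was tested separately.

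Genes raised at least 2-fold by 4HBA lay next to each other more often than shuffled calls, and this was not particular to them. In T. versicolor 16 of the neighbouring pairs were raised together against 2.46 on average in 10000 shuffles, and 7 against 0.829 among neighbours over 1 kb apart, a ratio of 8.44 (permutation p = 1e-04, the smallest these shuffles can give). Transcripts running on from a neighbour would not be expected at that distance, which argues against them for those pairs. In G. subvermispora, where distances are unknown, neighbours were judged by the order of gene numbers, and whether this is genome order was not checked. There 11 pairs were raised together against 3.40, a ratio of 3.24 (permutation p = 0.0004), which argues against random placement in that order. Lowered genes also formed more pairs than shuffled calls, with 17 against 3.29 in T. versicolor and 26 against 2.82, a ratio of 9.20, in G. subvermispora. The 4HBA group of G. subvermispora mixes library types, and its genes above 1% of counts include a run of gene numbers from 10787 to 10794. Library type was not separated from these lowered pairs. The other additions and poplar also gave more pairs than shuffled calls, except for poplar rises over 1 kb apart in T. versicolor (92 against 80.3, permutation p = 0.0993). Clusters of genes with a shared response, or neighbouring copies that share reads, may account for it, and neither was tested.

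With 6 libraries per comparison there are 10 splits into equal groups, too few for a share under 0.05, and in each comparison 1 of the 10 splits, the real one, called as many genes. The real splits called 2011, 6090, 6138, 8752, 5929 and 1075 genes in T. versicolor and 3417, 6137, 5138, 8264, 5602 and 3653 in G. subvermispora, in the order 4HBA, syringic acid, lignin and poplar against cellobiose, syringic acid against 4HBA, and lignin against syringic acid. The highest of the other splits called 0 genes in edgeR in all 12 comparisons. Each of those splits mixes libraries of both groups, and the spread was estimated again on the mixed groups. Where the groups differ this widens the spread, so few calls were likely from the start and are no independent support. At an unadjusted p below 0.05 the highest of the others had 1063, 1694, 825, 280, 1632 and 3108 genes in T. versicolor against 3655, 6897, 6875, 8967, 6803 and 3006 in the real splits. In G. subvermispora the highest had 1169, 678, 485, 424, 1406 and 827 against 4573, 6639, 5883, 8421, 6213 and 4725. For lignin and syringic acid in T. versicolor the value of 3108 against 3006 means that unadjusted counts do not set the real split apart. The source of that value was not tested.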
